A study of Mus musculus with 2 samples.

How the data were processed

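The material was spinal cord from C57BL/6J mice aged at least 12 weeks, per the labels. Tissue segments of 5 mm were dissociated with papain, myelin was removed on sucrose, tdTomato-positive cells were sorted, and libraries were made with a 10x Genomics 3′ kit, all per the labels' protocols. There was 1 uninjured library and 1 library from day 3 after a dorsal funiculus incision. Per the submitters' processing notes, Cell Ranger 3.0.1 and Seurat were used with the mm10 build. The version of Seurat, the role of each tool and the gene annotation are not given in the sources used here.

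The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell, which the authors left unnormalised, as their whole numbers and unequal totals per cell show. A table per library held 876 uninjured and 1566 injured barcodes with 15624 and 16957 genes, each gene seen in at least 3 cells of its table. The authors' table of all kept cells named 711 and 1228 of these barcodes, and the table of EpA cells named 555 and 1004 of them. The table of all kept cells lists 13999 genes and was used only for its list of cells. Values of shared cells and genes were identical between the tables. The 18 barcode sequences found in both libraries were kept apart by library.

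UMIs were summed over the EpA cells of each library and scaled to counts per 1000000 UMIs (CPM) of the library's EpA total. A log2 ratio of injured over uninjured was taken with 0.5 counts added. Levels carry exact 95% Poisson intervals, ratios exact conditional binomial intervals and shares exact binomial (Clopper-Pearson) intervals, all for counting error only. They say nothing of variation between animals, since cells are not replicates. A gene with no recorded UMI in 1 library was set against a floor of 3 counts over that library's sum. This included genes that the library's table did not list, which were taken as 0. Genes were called higher or lower by size alone, with at least 50 CPM in either library and a 2-fold ratio. The totals of 7689179 and 25296289 UMIs put 50 CPM well above a single UMI.

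The gene lists, cell type markers, size rule, rule for named genes, share rules and most alternatives were chosen before the data were examined. Named genes were the 12 largest and 12 smallest ratios that met the size rule, up to 4 members with the largest ratios from each list, and 14 fixed genes. Predicted and clone-named genes, mitochondrially encoded genes and ribosomal protein genes were left out of the first group and only counted. Some genes that these rules name are not reported here. The left-out kinds made up 46 of the higher genes, 37 of them ribosomal protein genes, and 59 of the lower genes, 6 of them mitochondrially encoded. The lists covered motile cilium, ependymal identity, neural stem and progenitor, S phase, G2 and mitosis, reactive glia, interferon response, MHC class I presentation, extracellular matrix, cytoskeleton and migration, immediate early, heat shock, glycolysis, cholesterol synthesis, endoplasmic reticulum stress, metallothionein and antioxidant, cytokine and NF-kB, Notch pathway, Wnt target, ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation and sex-linked genes. A member counted as measured at a mean of at least 5 CPM. The median of a list carries an interval from 1000 Poisson redraws, and its percentile among 10000 random lists of equal size, matched on expression in 20 bins, describes these libraries and is not a test.

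For shares and list contents per cell, each cell was thinned to 2000 UMIs, which left out 8 uninjured and 12 injured EpA cells. The 711 and 1228 kept cells were clustered jointly on 2000 variable genes, 20 principal components and 15 neighbours with the Leiden method at resolution 0.5. A cluster was given a cell type name only with at least 3 fixed markers above 100 CPM, and fixed markers of that class and not more than 1 of any other among its top 10 genes. A cluster made mostly of EpA cells took no name but ependymal-like. These conditions were not fixed in advance of the data, and the limit on other classes was added after the clusters had been seen. Scrublet called 4 of 876 and 4 of 1566 barcodes doublets, 1 and 3 of them EpA cells. So few calls do not show that doublets were absent, and no cell was removed for it except in an alternative.

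Tested on counts simulated from these libraries, with 200 of the genes changed, the size rule recovered 50 of 50 genes made 4-fold higher, 50 of 50 made 4-fold lower, 50 of 50 made 3-fold higher and 49 of 50 made 3-fold lower. It took none of 3010 unchanged genes past the floor, and 95.6% of true ratios lay inside their intervals. The simulated counts were Poisson draws from 1 pooled profile, without variation between cells, libraries or animals. These results thus check the calculation at this depth and give no error rate for the comparison of the 2 libraries. Alternatives covered scaling (TMM of edgeR, totals without mitochondrial and ribosomal protein genes, cells weighted alike, thinned cells), the cells used, doublets, CPM floors, list membership, the added count and the share rules. UMIs per cell without scaling, shorter lists of mitosis genes, and EpA cells without markers of other classes were alternatives chosen after seeing the data. Gene positions come from GENCODE M21 on GRCm38, where 16552 of 17189 gene symbols were found once. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.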

Results

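The experiment asked how EpA cells, a subset of the ependymal cells that line the central canal of the spinal cord, differ in their transcripts after a spinal cord injury. Cells carrying the red fluorescent protein tdTomato were sorted from adult mice at least 12 weeks old, in which the Troy-CreERT2 allele drives recombination of a Rosa26-tdTomato reporter. CreERT2 is a recombinase that acts in the presence of tamoxifen, and Troy is another name of the gene Tnfrsf19. One condition was the intact cord and the other the cord 3 days after an incision of the dorsal funiculus, with a 5 mm segment taken around the lesion or at the matching level. There was 1 library of single-cell 3′ RNA sequencing per condition, so no difference below has a replicate check and no test between conditions was made. Bracketed ranges are 95% intervals for counting error only.

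The authors' set of EpA cells held 555 cells of the uninjured library and 1004 cells of the injured library, with 7689179 and 25296289 unique molecular identifiers (UMIs). The median cell had 11387 UMIs in the uninjured and 20158.5 in the injured library. Mitochondrially encoded transcripts made up a median of 11.2% and 6.76% of a cell's UMIs. The sort marker was present in both libraries. Transcripts of tdTomato stood at 645 CPM (counts per 1000000 UMIs; 627 to 664) in uninjured and 1716 CPM (1699 to 1732) in injured EpA cells, against 37.3 and 122 CPM in the microglia-like cells of the same libraries, a type that should lack the reporter. It did not set EpA cells apart from the rest of the sort, since the kept cells outside the EpA set stood at 733 and 1779 CPM, cluster 6 at 1377 and 2714 CPM and cluster 10 at 789 and 944 CPM. The driver gene itself, Tnfrsf19, was sparse, at 16.6 CPM in uninjured and 9.25 CPM in injured EpA cells. The Y-linked gene Ddx3y was detected in both libraries (62.7 and 41.6 CPM), and Xist, expressed from the inactive X chromosome, was at 0.78 and 0.158 CPM. None of the 4 measured sex-linked genes differed 2-fold (median log2 ratio −0.41, −0.54 to −0.25; percentile 16.5).

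In sums over cells, EpA cells of the injured cord carried fewer transcripts of the motile cilium, the beating organelle of ependymal cells. They carried more transcripts of the lists for cytoskeleton and migration, cell division and reactive glia. These sums average over injured cells that differed from each other, as given below. Of 43 measured cilium genes, 39 were at least 2-fold lower in the injured library and none was 2-fold higher. The list's median log2 ratio of injured over uninjured was −1.48 (−1.50 to −1.42), a 2.78-fold lower level. In the opposite direction, Gfap, the intermediate filament protein of astrocytes, was 65.2-fold higher (51.2 to 84.3), and Nes, encoding the progenitor filament nestin, was 38.5-fold higher (29.4 to 51.5). Mki67, a marker of proliferating cells, was 23.5-fold higher (16.7 to 34.3).

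Across 3706 genes with at least 50 CPM in either library, 402 were at least 2-fold higher and 511 at least 2-fold lower in injured EpA cells. The lower bound of the ratio was itself at least 2-fold for 337 of the higher genes, and 440 of the lower genes cleared the same mark. Differences upwards were the more extreme: 74 genes were 10-fold or more higher, whereas 34 were 4-fold or more lower. The median log2 ratio over the 3706 genes was 0.00. These counts rest on sums in which deep cells weigh more. With every cell weighted alike, 211 genes were 2-fold higher and 131 lower, and with each cell thinned to 2000 UMIs the counts were 229 and 167, so that the higher genes made up 61.7% and 57.8% of the differing genes in place of 44.0%. As UMIs per cell without scaling, 1570 were higher and 55 lower, and with no CPM floor 3309 and 2747.

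**Figure D1:**
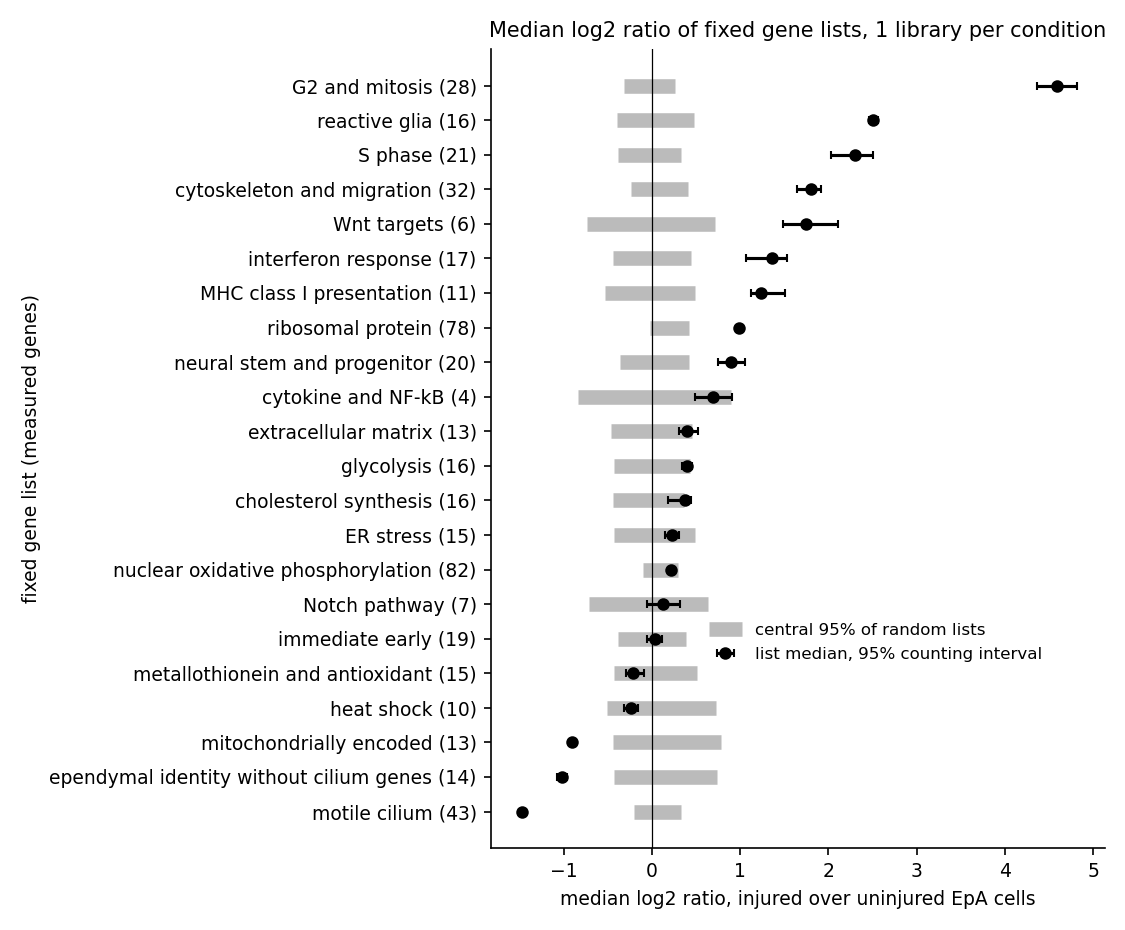
Median log2 ratio of injured over uninjured EpA cells for 22 gene lists fixed in advance, with 1 library per condition. Points are list medians with 95% counting intervals, grey bars span the central 95% of 10000 random lists matched on expression, numbers in brackets are measured genes, and the medians run from −1.48 for motile cilium to 4.59 for G2 and mitosis genes.

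The largest differences towards higher levels included genes that were nearly silent in uninjured EpA cells. Crym, encoding the thyroid hormone binding protein mu-crystallin, was at 1.04 CPM (0.449 to 2.05) in uninjured and 1115 CPM (1102 to 1128) in injured EpA cells, a ratio of 1072 (544 to 2483). Vgf, the precursor of secreted neuropeptides, and Nkx6-2, a homeobox transcription factor, stood at 68.9 and 62.1 CPM in injured EpA cells. Neither was listed for the uninjured library, whose listed genes were each seen in at least 3 cells. UMIs in fewer uninjured cells would therefore not show. Against a floor of 3 counts over the uninjured sum, they would be 177-fold and 159-fold higher, but these values are not strict bounds. Timp1, an inhibitor of matrix metalloproteinases, was 359-fold higher (174 to 894), and Spp1, the secreted matrix protein osteopontin, 271-fold higher (187 to 408). Spp1 was more abundant still among the sorted cells outside the EpA set, at 2929 CPM in the injured library. Timp1 was also higher there, at 513 CPM against 327 CPM in injured EpA cells. Emp3, a membrane protein, was 219-fold higher (115 to 479), Chl1, an adhesion molecule of the L1 family, 191-fold higher (87.6 to 521), and Tubb2b, a beta-tubulin, 189-fold higher (95.6 to 437). Emp3 was at 274 CPM outside the EpA set of the injured library, against 256 CPM in injured EpA cells. The other genes named in this paragraph were lower outside that set than in injured EpA cells. Some ratios rested on 1 to 3 uninjured UMIs and were therefore loosely bounded. They were 649 (116 to 25645) for Gap43, a growth cone protein, 204 (56.4 to 1688) for Spry1, an inhibitor of receptor tyrosine kinase signalling, and 141 (48.2 to 686) for Ccnb1, cyclin B1.

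The largest differences towards lower levels were smaller in size, among genes at 63.7 (Cdr1) to 1745 CPM (Rarres2) in uninjured EpA cells. Ccdc153, a coiled-coil gene of multiciliated cells, was at 1702 CPM (1673 to 1732) in uninjured and 295 CPM (289 to 302) in injured EpA cells, 5.76-fold lower (5.6 to 5.93). Rarres2, encoding the secreted protein chemerin, was 4.71-fold lower (4.59 to 4.84), and Pcp4, a regulator of calmodulin, 4.79-fold lower (4.59 to 5.00). The calcium-binding protein gene Calb1 was 4.49-fold lower (4.06 to 4.96). Clec3b, encoding tetranectin, was 4.84-fold lower (4.43 to 5.28), and the serotonin receptor gene Htr5b was 5.61-fold lower (4.91 to 6.43). Ccdc33, Cdr1, Ttll9, Lrrc74b, Fam166b and Rit2 completed the 12 lowest, with log2 ratios of −2.30, −2.26, −2.24, −2.23, −2.21 and −2.21.

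In the GENCODE M21 annotation of build GRCm38, Crym spans positions 120186380 to 120202111 of chromosome 7 and Ccdc153 spans 44240676 to 44247306 of chromosome 9. Gfap lies at 102887336 to 102900912 of chromosome 11 and Timp1 at 20870166 to 20874735 of chromosome X. All 4 are protein-coding genes, and 3′ sequencing counts their transcripts whole, without separating exons or isoforms.

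**Figure D2:**
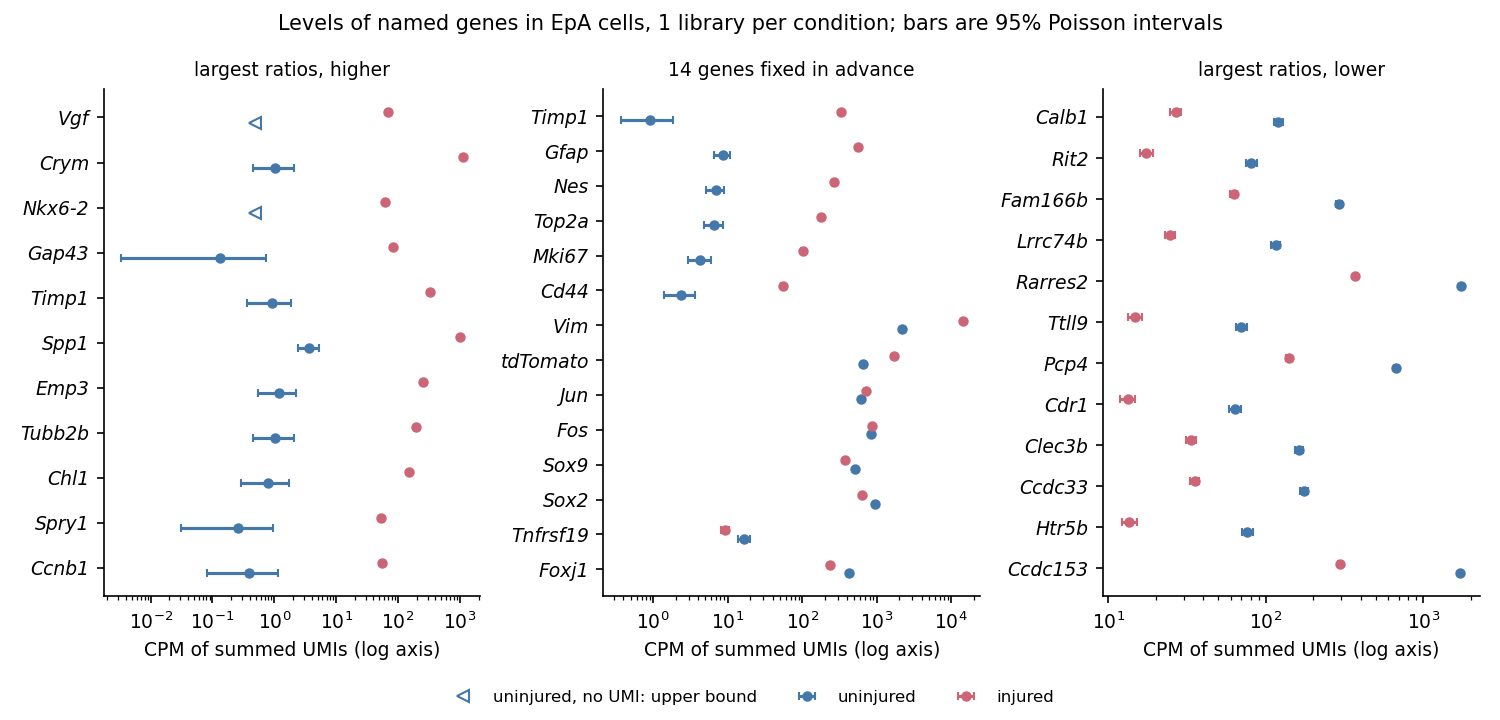
CPM of summed UMIs in EpA cells (log axis) for genes with the largest ratios in each direction and 14 genes fixed in advance, with uninjured values in blue and injured values in red. Bars are 95% Poisson intervals, and open triangles mark the upper bound where no uninjured UMI was recorded. Vgf and Nkx6-2 were not listed for the uninjured library, so their bound does not cover UMIs in fewer than 3 cells.

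Motile cilium genes were lower almost without exception. Hydin, needed for the central pair apparatus of the axoneme, was 4.20-fold lower (3.88 to 4.55), Tmem212 4.24-fold lower (4.13 to 4.36) and the outer dense fibre gene Odf3b 4.09-fold lower (3.87 to 4.32). The 4 members that differed by less than 2-fold were Tppp3 (log2 ratio 0.03) and the transcription factors Foxj1 (−0.86), Rfx2 (−0.94) and Rfx3 (−0.78), which drive the cilium gene programme. Foxj1, the master regulator among them, was at 421 CPM in uninjured and 233 CPM in injured EpA cells, and its log2 ratio was 0.01 when UMIs per cell were taken without scaling. The list's median lay below all 10000 matched random lists (percentile 0). It was −0.81 with every cell weighted alike, −0.89 with thinned cells and −0.61 as UMIs per cell without scaling.

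The cilium difference was uneven across cells. At 2000 UMIs per cell, cilium genes made up a median of 1.80% of the UMIs of an uninjured cell and 0.800% of those of an injured cell. Among 992 injured EpA cells, 550 (55.4%, 52.3 to 58.6) lay below the 5th percentile of the 547 uninjured cells, and 442 lay at or above it. Before thinning, the median UMI total was 28540.5 in the 550 cells and 11700 in the 442. Of the 992 injured cells, 116 were within 20% of the dividing value, 1.15% of UMIs. Foxj1, itself a member of the list that split the cells, was at 127 CPM in the 550 and 537 CPM in the 442. It was at 429 CPM in uninjured cells at or above the dividing value. In the sums over all EpA cells, 7 of 14 other ependymal genes were at least 2-fold lower and none higher, with a median log2 ratio of −1.02 (−1.08 to −0.97; percentile 0.02). This median was −0.45 with every cell weighted alike, −0.48 with thinned cells and −0.16 as UMIs per cell without scaling. Among them were Mia (−1.60), the lipid transfer gene Pltp (−1.81) and the imprinted gene Nnat (−1.48), while Cd24a, a surface protein of ependymal cells, was at 0.57 and the membrane linker Ezr at 0.01.

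**Figure D3:**
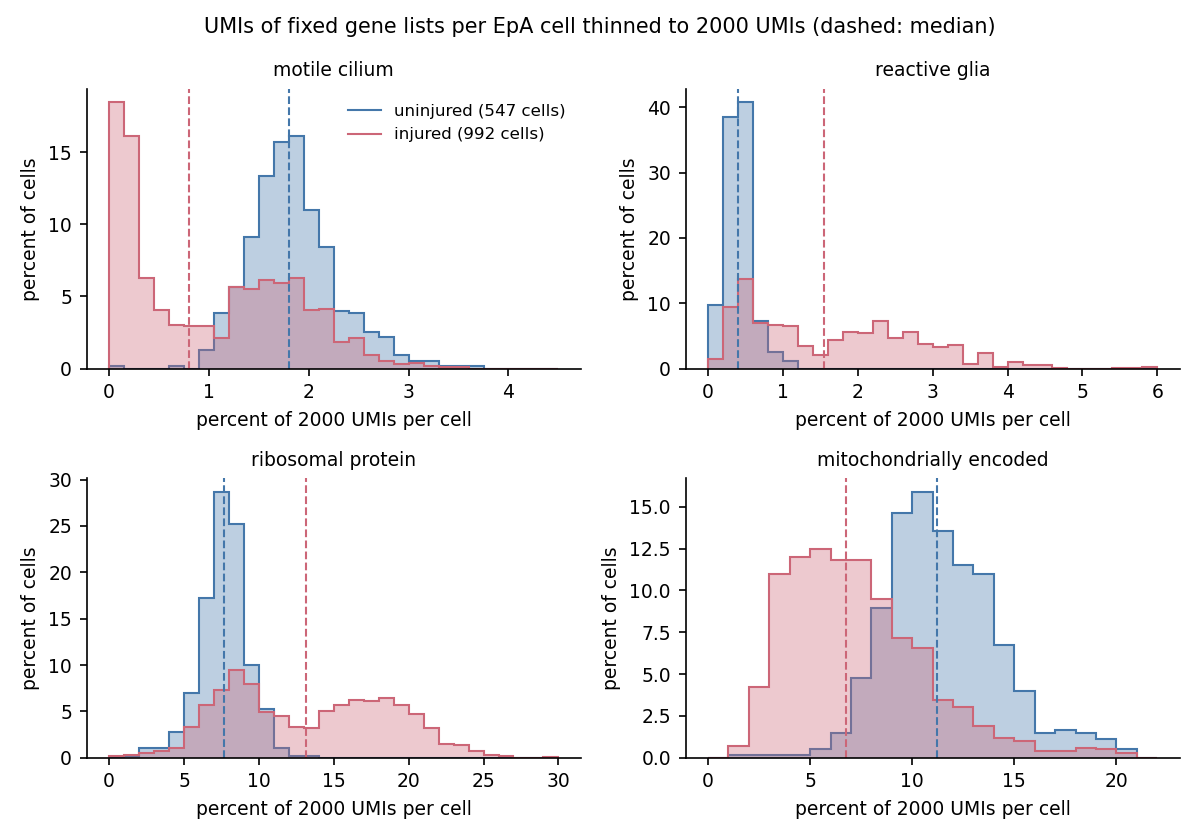
Percent of EpA cells (vertical axes) by the percent of a cell's 2000 UMIs that falls in each of 4 gene lists (horizontal axes), for 547 uninjured cells in blue and 992 injured cells in red, with dashed lines at the medians. The cilium panel shows injured cells in 2 groups, near 0 and within the uninjured range, and the ribosomal protein median is 7.65% in uninjured and 13.1% in injured cells.

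Genes of neural stem and progenitor cells did not move together. Of 20 measured, 9 were at least 2-fold higher, 1 was lower and 10 were in between, with a median log2 ratio of 0.90 (0.75 to 1.06; percentile 100). The higher members included Nes, Vim (6.43-fold, 6.34 to 6.53), the fatty acid binding protein gene Fabp7 (10.7-fold, 9.76 to 11.6) and the helix-loop-helix regulators Id1 (log2 ratio 4.66) and Id3 (5.24). The lower member was Ccnd2, cyclin D2 (−1.43). The stem cell transcription factors Sox2 (−0.61) and Sox9 (−0.43), and the driver gene Tnfrsf19 (−0.85), were below 0, and all 3 were above 0 as UMIs per cell without scaling, at 0.25, 0.43 and 0.01.

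Cell cycle genes were higher in the sums. Of 28 genes of G2 and mitosis, 25 were at least 2-fold higher, 1 was lower (Pttg1, securin, −1.28) and 2 were in between, with a median log2 ratio of 4.59 (4.36 to 4.82; percentile 100). Top2a, the topoisomerase of dividing cells, was 27.4-fold higher (20.7 to 36.9). Cenpa, the centromere histone, was at 1.30 and 102 CPM, and Ube2c, a mitotic ubiquitin-conjugating enzyme, at 1.69 and 155 CPM. Of 21 measured S phase genes, 18 were at least 2-fold higher and none lower (median log2 ratio 2.31, 2.03 to 2.5; percentile 100), among them Mcm5 of the replicative helicase (3.21) and cyclin E2, Ccne2 (3.58). The uninjured level rested on few cells: 27 of the 33 Mki67 UMIs of uninjured EpA cells came from 1 cell, without which the Mki67 ratio was 129 (59.3 to 352). The G2 and mitosis median was 2.02 with every cell weighted alike. The S phase median was 1.15 with cells weighted alike, 1.29 with thinned cells and 0.41 without cells holding at least 2 G2 and mitosis genes. Against uninjured cells in the cilium range, the G2 and mitosis median was 5.94 in the 550 injured cells below that range. It was −0.095 in the 442 within it, and the S phase medians were 2.79 and −0.34. Mki67 was at 136 CPM in the 550 cells and 0.921 CPM in the 442, against 0.681 CPM in those uninjured cells. The uninjured cells in range do not include the cell with 27 of the 33 Mki67 UMIs, which lay below the range. Over all uninjured EpA cells Mki67 was at 4.29 CPM.

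The share of cells with cell cycle transcripts depended on the rule. By the rule fixed in advance, at least 2 of the 28 G2 and mitosis genes in 2000 UMIs, 130 of 547 uninjured cells (23.8%, 20.3 to 27.6) and 277 of 992 injured cells (27.9%, 25.2 to 30.8) qualified, and the intervals overlapped. Without thinning the shares were 91.5% and 90.5%, so the rule also counted cells with stray UMIs of genes that uninjured cells express, such as Pttg1 (285 CPM) and Hmgb2 (141 CPM). With at least 3 genes the shares were 5.85% (4.04 to 8.16) and 15% (12.9 to 17.4). Under a rule chosen after seeing the data, at least 2 of 10 core genes, they were 0.548% (0.113 to 1.59) and 10.6% (8.74 to 12.7). Among sorted cells outside the EpA set, the planned rule gave 9.92% (5.23 to 16.7) and 40.5% (33.7 to 47.5), but these were not the same kinds of cells, since cluster 5 held 5 uninjured and 81 injured of them and cluster 9 held 30 and 6.

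**Figure D4:**
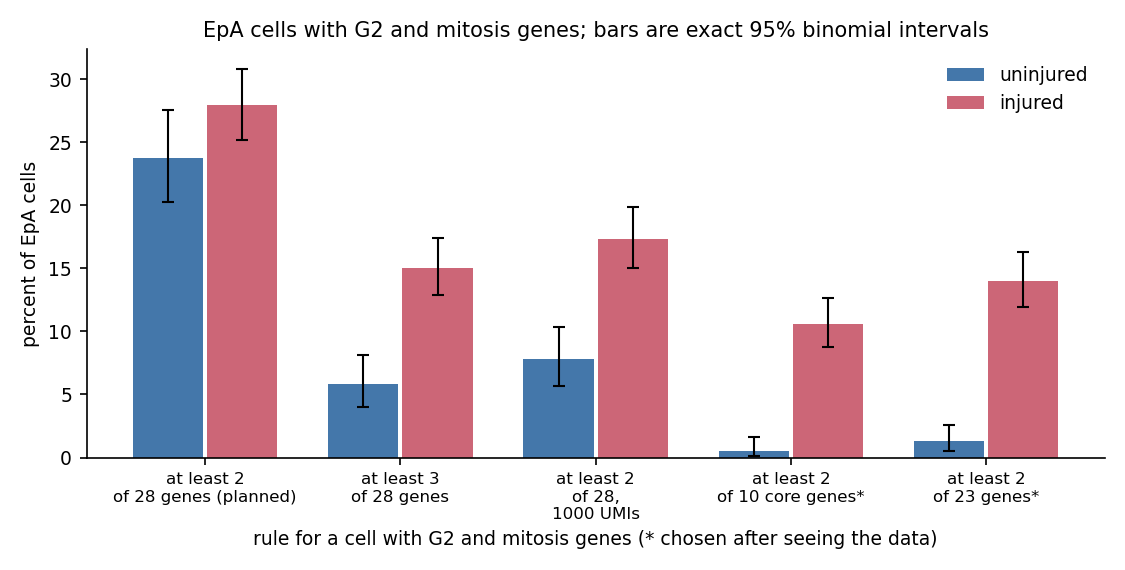
Percent of EpA cells that meet each of 5 rules for G2 and mitosis transcripts, in the uninjured (blue) and injured (red) library, with exact 95% binomial intervals. Asterisks mark rules chosen after seeing the data; the planned rule gives 23.8% and 27.9%, and the rule with 10 core genes 0.548% and 10.6%.

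Genes of reactive glia were higher. Of 16 measured, 12 were at least 2-fold higher and none was 2-fold lower, with a median log2 ratio of 2.51 (2.46 to 2.56; percentile 100). Besides Gfap, Vim and Timp1, the hyaluronan receptor Cd44 was 23.7-fold higher (14.9 to 40.1) and the oncostatin M receptor Osmr 30.2-fold higher (13.8 to 82.7). Serpina3n, a protease inhibitor induced in reactive astrocytes, was not detected in uninjured EpA cells and was at 37.8 CPM in injured ones. It would be 97.0-fold higher against the floor of 3 counts, and the lower bound of its ratio was 78.7. With this gene at its ratio against that floor the list median was still 2.51. At 2000 UMIs per cell, 680 of 992 injured cells (68.5%, 65.6 to 71.4) lay above the 95th percentile of uninjured cells for this list. Vim made up 14246 of the measured members' 20523 CPM in injured and 2214 of 3976 CPM in uninjured EpA cells. The count of 680 cells thus reads mostly Vim. At that depth Gfap was seen in 2.29% of uninjured cells in the cilium range and 25.1% of the 442 such injured cells. In the 550 injured cells below that range it was seen in 51.1%.

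Antiviral and antigen presentation genes were higher as well. Of 17 interferon response genes, 11 were at least 2-fold higher and none lower (median log2 ratio 1.36, 1.07 to 1.53; percentile 100). Bst2, encoding tetherin, was 6.89-fold higher (5.53 to 8.69) and the ubiquitin-like modifier Isg15 8.44-fold higher (4.76 to 16.5), whereas the transcription factor Irf1 was at a log2 ratio of −0.10. For MHC class I presentation, 8 of 11 genes were higher and 1 lower (median 1.23, 1.12 to 1.5; percentile 100). B2m, the class I light chain, was at 19.2 CPM in uninjured and 188 CPM in injured EpA cells, H2-D1 at 45.4 and 187 CPM, and the lower member was the peptide transporter subunit Tap2 (−1.03). The interferon median was 0.99 with cells weighted alike and 0.85 in EpA cells with at least 1000 UMIs and under 10% mitochondrially encoded UMIs. Over all deposited barcodes instead of EpA cells it was 0.49, and the class I median was −0.090. In the 442 injured EpA cells within the uninjured cilium range the interferon median was 1.23 and the class I median 1.10. In the 550 cells below it they were 1.34 and 1.39, each against uninjured cells in range.

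The cytoskeleton list had 26 of 32 genes at least 2-fold higher and none lower, with a median log2 ratio of 1.80 (1.65 to 1.91; percentile 100). Lgals1, encoding galectin-1, was 115-fold higher (96.7 to 138), the actin-binding transgelin gene Tagln 42.0-fold higher (35.0 to 50.8), and the tubulin genes Tubb6 and Tuba1c had log2 ratios of 6.23 and 5.20. The major neural alpha-tubulin gene Tuba1a was at −0.47. Against uninjured cells in the cilium range, the list's median was 2.14 in the 550 injured cells below that range and 0.45 in the 442 within it. Extracellular matrix genes were mixed, with 5 of 13 higher, 1 lower and a median of 0.40 (0.31 to 0.52; percentile 95.8). The glial scar glycoproteins Tnc (33.3-fold, 16.1 to 83.1) and Vcan (11.4-fold, 8.71 to 15.2) and fibronectin, Fn1 (8.24-fold, 6.79 to 10.1), were higher, while the proteoglycan gene Ncan was lower (−1.11). Over the alternatives the log2 ratio of Tnc ran from 0.23 to 5.89.

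Ribosomal protein genes had 38 of 78 members at least 2-fold higher and none lower, with a median log2 ratio of 0.98 (0.97 to 1.0; percentile 100), led by Rpl39 (1.84), Rpl6l (1.78), Rps2 (1.70) and Rps26 (1.68). Of these, Rpl6l is annotated as a processed pseudogene and was at 7.28 and 25.2 CPM. Mitochondrially encoded genes had 6 of 13 lower and none higher, with a median of −0.91 (−0.93 to −0.88; percentile 0.055), among them mt-Nd2 (−1.24) and mt-Nd4 (−1.16). This median was −0.04 as UMIs per cell without scaling. The nuclear genes of oxidative phosphorylation had no member past 2-fold among 82 (median 0.22, 0.19 to 0.25; percentile 85.3). Glycolysis genes had 5 of 16 higher and 1 lower (median 0.40, 0.35 to 0.45; percentile 96.4), with lactate dehydrogenase A, Ldha, 3.59-fold higher (3.31 to 3.89) and the glucose transporter gene Slc2a1 lower (−1.59).

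Some lists lay within the central 95% of matched random lists. The immediate early genes had 4 of 19 higher and 2 lower (median 0.03, −0.06 to 0.11; percentile 55.6), with Fos at 834 and 877 CPM and Jun at 622 and 717 CPM. Fosl2 (3.35) and Ier3 (3.11) were higher, and Klf2 (−1.65) lower. Heat shock genes had 1 of 10 higher and 2 lower (median −0.24, −0.31 to −0.16; percentile 11.3), with Hspb1 at 2.46 and Hspa1b at −1.52. Endoplasmic reticulum stress genes had 2 of 15 higher and none lower (median 0.22, 0.15 to 0.30; percentile 78.6), with Asns at 2.49. Metallothionein and antioxidant genes had 3 of 15 higher and 1 lower, with a median of −0.21 (−0.29 to −0.09; percentile 11.8) and a mean of 0.22, since Hmox1 (4.04) and Srxn1 (2.24) stood far above the rest. Of the Notch pathway, 1 of 7 genes was higher (Hes1, 1.19) and 1 lower (Dll1, −1.73), with a median of 0.12 (−0.05 to 0.32; percentile 69.9). The cytokine list kept 4 genes, 2 of them higher (C3, 4.37, and Nfkbiz, 1.04), with a median of 0.69 (0.48 to 0.91; percentile 95.1). As UMIs per cell without scaling, where the median log2 ratio of the 3706 genes was 0.87, the heat shock median was 0.63 and the metallothionein and antioxidant median 0.65. Cholesterol synthesis genes lay just above that range, with 3 of 16 higher, none lower and a median of 0.37 (0.18 to 0.44; percentile 97.6).

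Of 6 measured Wnt target genes, 3 were higher and none lower, with a median of 1.75 (1.48 to 2.11; percentile 99.9). The higher members were Ccnd1, cyclin D1 (36.7-fold, 28.3 to 48.3), Myc (26.0-fold, 13.1 to 60.5) and the stem cell receptor gene Lgr5 (12.1-fold, 8.29 to 18.5). The feedback genes Axin2 (−0.28), Nkd1 (−0.79) and Znrf3 (−0.08) were not higher in the injured library under total scaling. The median of 1.75 lies in the gap between Znrf3 and Lgr5 (log2 ratio 3.58), where no member stood. Over all deposited barcodes the list's median was −0.37.

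Markers of other cell types were read in the same EpA sums. Members of fixed lists named here and above outside the rule for named genes, such as Pttg1, Tppp3, Ccnd2, Tap2 and Tuba1a, were chosen after their values were seen. No macrophage, neutrophil, lymphocyte, pericyte, Schwann cell or erythrocyte marker reached a mean of 5 CPM. The fibroblast gene Col1a2 was at 28.9 and 32.3 CPM, the endothelial gene Kdr at 13.9 and 2.81 CPM and Gata3, of neurons that contact the cerebrospinal fluid, at 7.02 and 5.65 CPM. Among markers at least 2-fold higher in injured EpA cells were the smooth muscle genes Acta2 (27.8 and 120 CPM) and Cnn1 (2.21 and 37.8 CPM), the neuronal genes Stmn2 (152 and 635 CPM) and Tubb3 (0.52 and 10.2 CPM), although the neuronal gene Meg3 was lower (649 and 347 CPM), and the oligodendrocyte progenitor genes Olig1 (0.13 and 24.9 CPM) and C1ql1 (0.39 and 12.2 CPM). Of 8 ependymal markers, 7 were lower and none higher (median −1.58, −1.61 to −1.56; percentile 0). Apart from Mia, which is on the ependymal identity list, these markers are all members of the motile cilium list. Their result therefore repeats those lists and is not separate evidence. Of 6 measured astrocyte markers, Aldoc (1.65) and Aldh1l1 (4.46) were higher, and Aqp4 (−0.94) and Gja1 (−0.08) were not.

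The sort also held cells that the authors did not count as EpA. They were 156 of 711 kept cells in the uninjured library (21.9%, 19 to 25.2) and 224 of 1228 in the injured library (18.2%, 16.1 to 20.5). The gate and the authors' filters can set these shares. Among cells with at least 1000 UMIs and under 10% mitochondrially encoded UMIs they were 38.5% (32.8 to 44.4) and 18.8% (16.5 to 21.4). Joint clustering gave 11 clusters, of which clusters 5 to 10 consisted almost entirely of such cells. Cluster 7 was microglia-like (C1qa, C1qb and Cx3cr1 among its top genes), cluster 8 fibroblast-like (Dcn, Col3a1, Col1a1) and cluster 9 astrocyte-like (Slc1a2, Agt). Cluster 5 had all 8 endothelial markers above 100 CPM but none among its top genes and stayed unnamed, as did cluster 6, led by haemoglobin and endothelial genes, and cluster 10, led by Cd74 and Cd79a.

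Clusters 0 and 3 were ependymal-like and contained 547 of the 555 uninjured EpA cells. Of the 1004 injured EpA cells, 376 (37.5%, 34.4 to 40.5) fell in them. The other injured EpA cells lay in clusters 1, 2 and 4, with 287, 223 and 118 cells. These clusters were made almost entirely of the injured library, were left unnamed, and with 1 library per condition do not separate a cell state from a library. Their sizes were not compared between conditions. Among the top genes of cluster 4 were Pbk, Prc1 and Fam64a, of which Prc1 is on the G2 and mitosis list. Cluster 4 also had neutrophil genes such as S100a8 and S100a9 among its top genes and 4 of 7 neutrophil markers above 100 CPM. All 18851 UMIs of these markers lay in its 4 uninjured cells outside the EpA set, and its 122 EpA cells had 0. It stayed unnamed because 122 of its 130 cells were EpA cells. Ependymal markers, which are motile cilium genes apart from Mia, were above 100 CPM for 8 of 8 in cluster 1, 4 of 8 in cluster 2 and 0 of 8 in cluster 4.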

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

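A group of barcodes that the authors left out of their kept cells stood apart by its low share of mitochondrially encoded UMIs, and was used above only in the values over all deposited barcodes. Barcodes with under 1% of such UMIs were 87 of 876 in the uninjured library (9.93%, 8.03 to 12.1) and 237 of 1566 in the injured library (15.1%, 13.4 to 17), where the lowest shares among kept cells were 1.26% and 1.01%. Their median UMI totals were 1346 and 1746. Malat1, a nuclear RNA, was at 5036 and 3614 CPM in them, against 68061 and 42414 CPM in EpA cells, and ribosomal protein genes were at 150562 and 229770 CPM, against 76416 and 154845 CPM. Motile cilium genes were at 21917 and 6991 CPM, and tdTomato at 798 and 2052 CPM. No explanation was tested.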

How the results depend on the processing

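No paired analysis was possible, since there was 1 library per condition and the labels do not pair them. UMIs per cell without scaling, 10 core genes and the list without 5 abundant genes were chosen after seeing the data. Where no construction is named, the cause was not tested. Over the alternatives, list medians moved beyond their interval 117 times and stayed within it 122 times, and named genes did so 510 and 595 times. Among results at least 2-fold in the primary analysis, 3 list medians and 2 named genes reversed. Counting smaller values too, 7 of 22 list medians and 18 of 123 named genes took both signs, among them heat shock, immediate early, Notch pathway and metallothionein and antioxidant genes, Foxj1, Sox2, Sox9, Tnfrsf19, Fos and Jun. With TMM scaling the medians were −1.41 for motile cilium, −0.96 for ependymal identity and 2.58 for reactive glia. With cells weighted alike, 211 genes were 2-fold higher and 131 lower, and the medians were −0.81 for motile cilium, −0.45 for ependymal identity, 2.02 for G2 and mitosis and 2.03 for reactive glia. With cells thinned to 2000 UMIs there were 229 higher and 167 lower genes, and the medians were −0.89, −0.48, 3.87 and 2.07 in that order, 0.63 for neural stem and progenitor genes, and −0.24 for the gene Cyp51, whose direction reversed. Over all deposited cells, which adds both the other kept cells and the barcodes the authors left out, the medians were −1.53 for motile cilium, −1.24 for ependymal identity, 0.39 for neural stem and progenitor, 3.92 for G2 and mitosis and 1.55 for reactive glia. There MHC class I presentation (−0.090), Wnt targets (−0.37) and the gene H2-Q4 (−0.43) reversed. With EpA cells of at least 1000 UMIs and under 10% mitochondrially encoded UMIs, 176 uninjured and 819 injured cells, these 5 medians were −1.78, −1.17, 1.06, 3.99 and 2.31, and the uninjured share outside the EpA set was 38.5%. Without cells with at least 2 G2 and mitosis genes, 258 genes were higher and 311 lower, and the medians were −1.07 for motile cilium, −0.74 for ependymal identity and 2.43 for reactive glia. The G2 and mitosis median reversed to −0.033 by construction. As UMIs per cell without scaling, where the median of all genes shifted to 0.87, 1570 genes were higher and 55 lower, and the 5 medians were −0.61, −0.16, 1.76, 5.45 and 3.37. CPM floors of 20 and 100 gave 767 and 243 higher and 830 and 304 lower genes, and no floor gave 3309 and 2747, by the number of genes admitted. Reactive glia with all members with any UMI was 2.86, and G2 and mitosis with a prior of 5 counts 4.26. The share of cells with G2 and mitosis genes was 7.80% uninjured and 17.3% injured at 1000 UMIs, 91.5% and 90.5% not thinned, 5.85% and 15% with at least 3 genes, 0.548% and 10.6% with 10 core genes, and 1.28% and 14% without the 5 genes abundant in uninjured cells. Depth limits the ratios of genes with 1 to 3 uninjured UMIs.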

Other observations

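The tests of the motile cilium pattern and of free RNA in cells that keep cilium genes were chosen after the results were seen, as were the look at single cells, at ribosomal protein genes in other clusters and at reactive glia genes within clusters 0 and 3. The tests of RNA from other sorted cells and of reactive glia genes in cells that keep cilium genes were written before their results were seen. A single cell held most of the Mki67 signal of uninjured EpA cells. It had 20239 UMIs, at least 1 UMI of 24 of the 28 G2 and mitosis genes, and 20 of the 50 Top2a UMIs. Its 119 motile cilium UMIs were 0.588% of its total, below the 5th percentile of uninjured cells (1.15%), and it had 9 tdTomato and 6 Sox2 UMIs. Ependymal markers summed to 54 UMIs in it and neutrophil and endothelial markers to 0. It lay in cluster 4, which is unnamed, so its type is not settled by these values. Mki67 was seen in 6 of 555 uninjured and 172 of 1004 injured EpA cells, and without the cell the Top2a ratio was 45.5 (31.8 to 67.5).

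Ribosomal protein genes were also higher in injured cells of the 3 clusters outside the EpA set with at least 20 such cells per library. Their median log2 ratio was 0.24 (0.20 to 0.26) in cluster 6, 0.38 (0.33 to 0.42) in the microglia-like cluster 7 and 0.47 (0.42 to 0.49) in the fibroblast-like cluster 8, where median UMIs differed most, at 1131.5 and 19525. It was 0.98 over all EpA cells and 0.27 in the injured EpA cells whose cilium genes lay in the uninjured range. Mitochondrially encoded genes had medians of 0.05, 0.08 and −0.78 in the same clusters.

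Lower motile cilium genes in injured EpA cells were set against 3 technical explanations. Dilution by a larger UMI total alone would leave UMIs per cell as they were, but without scaling the list's median was −0.61 (−0.64 to −0.56), below a limit of −0.2 that was set with this value already known. The larger total, 0.86 on the log2 scale and dependent also on sequencing depth, thus goes with part of the −1.48. Without cells with at least 2 G2 and mitosis genes the median was −1.07, and with every cell weighted alike −0.81. Neither the cells left out nor deep cells alone thus account for the difference, although both changed its size. The cells left out were not all cycling, since that rule also counted stray UMIs. The 3 explanations were tested one at a time, so their joint effect stays open. Library preparation and injury cannot be told apart with 1 library each.

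Genes higher in injured EpA cells might come from RNA of the other sorted cells in EpA droplets. By the median over each class's markers, the largest share of EpA UMIs that such RNA was allowed was 0.810%, for astrocytes, among these, microglia, fibroblasts and the unnamed clusters 5 and 6, read with endothelial markers. Of the 402 higher genes, 0 could be given by that share of RNA of the other sorted cells in EpA droplets, and 24 (5.97%) by the largest share of any single marker, 10.9% for Aldh1l1, which was looked up after the results were seen. The median gene needed 38.3%, Timp1 14.1% and Spp1 4.17%, so single genes such as Spp1 are not excluded at the larger share. The 2 astrocyte shares rest on the 6 injured cells of cluster 9. Since a higher gene had at least 50 CPM, a share as small as 0.810% could give only genes very abundant in the other class. The count of 0 therefore adds little to the small share itself. Other cell types were not covered.

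A hypothesis was that reactive glia genes are higher also in injured EpA cells whose cilium genes lie in the uninjured range. In those 442 cells the list's median log2 ratio was 1.17, above the value of 1 set in advance, with 9 of 16 members at least 2-fold higher. The median over cells was 0.6% of UMIs, against 0.4% in uninjured cells in range and 2.35% in the 550 injured cells below it. These percents read mostly Vim. Of the 442 cells, 99 lay in cluster 1, led by C3 and Gfap, and 1 in cluster 2. In these 100 cells the median log2 ratio was 1.71 (1.58 to 1.96). In the 342 of clusters 0 and 3, looked at after the results, it was 0.61 (0.44 to 0.66) with 5 members 2-fold higher. Both were set beside 524 uninjured cells. A difference of at least 1 was not reached in clusters that uninjured cells share, but that value was set for the 442 cells only. These clusters were themselves formed on expression, so leaving out cluster 1 removed cells high in Gfap, a tested gene. The 1.17 thus rests in part on the 100 cells outside the shared clusters. Of the 992 injured cells, 116 lay within 20% of the dividing value. Free RNA of the injured EpA cells with few cilium genes may add to the difference and stays open. The 9 higher members needed a median share of 20.01% against the 7.02% that abundant genes of those cells allow. This lay between the 2 limits set for the test. Gfap, with a share of 46.0%, was counted on both sides, so the 2 sides are not independent. A later criterion, the lowest share among the abundant genes (1.03%), which all 9 exceeded, was picked after this outcome and is not relied on.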
